A study of Arabidopsis thaliana with 2 samples.

How the data were processed

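The data are gene counts from RNA sequencing of Arabidopsis thaliana rosette leaf explants that carry the pER8:3xFlag-NAC1 transgene in the Col-0 background. In this vector estradiol switches on the inserted gene, here a tagged copy of the transcription factor gene NAC1. Groups were taken from the treatment label. The estradiol group and the control group hold 1 library each, both from plants at 12 days after sowing, so there are no replicates. No test was run and no p-value is given. Every difference is between 2 libraries and is not a replicated effect of the conditions. Intervals of gene ratios and floors cover counting error only. They may be too narrow even for that, since reads without molecular identifiers are not independent molecules. Intervals of list and family medians reflect the spread among member genes instead. How long the explants were treated is not given in the sources used here.

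The authors deposited raw gene counts, 1 table per library, with whole numbers for 33602 loci and 5 summary lines. FastQC, HTSeq, DESeq and the TAIR10 assembly are named per the submitters' processing notes, without versions. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The 5 summary lines were kept out of library sizes. Reads counted as ambiguous were 2.05% of the control library and 1.91% of the estradiol library, and reads outside any annotated feature 0.742% and 0.693%. The 3 lines for reads aligned more than once, not aligned or of low quality hold 0 in both libraries, and all 279 loci of the organelle genomes are listed at 0.

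Total gene counts were 39799127 in the control library and 48350705 in the estradiol library. Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.993 and 1.007. A gene was measured if it had at least 10 counts in 1 or more libraries. The ratio of estradiol to control has an exact 95% interval (Clopper-Pearson, conditional on the sum of both counts). For equal counts of 10 in each library that interval runs from 0.374-fold to 2.68-fold, for 100 from 0.750-fold to 1.33-fold, and for 1000 from 0.915-fold to 1.09-fold. A gene is called higher or lower where its whole interval lies above 2 or below 0.5. Log2 ratios use a prior count of 0.5. A gene at 0 in a library is given a bound against a floor of 3 counts in that library. With TMM scaling this floor is 0.0759 CPM in the control and 0.0616 CPM in the estradiol library. A fold given as at least takes the count of the other library as exact. It therefore lies further from 1 than the limit of the exact interval, which was used for calls and ranking.

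The size rule was tested on simulated counts for this comparison, in steps of 20135 to 20141 genes. It called 44 of 50 genes made 3-fold higher, 49 of 50 made 4-fold higher, 50 of 50 made 8-fold higher and 47 of 50 made 4-fold lower. With counting error alone it called 0 of 19938 unchanged genes. With a coefficient of variation of 0.2 between libraries it called 141 of 20135 unchanged genes (0.700%), and with one of 0.4 it called 3174 of 20141 (15.8%). The share called at 0.4 is larger than that of all calls in this comparison, 5.38% of genes higher and 4.64% lower. The variation between libraries of this study cannot be estimated, so an unknown share of the calls may be such variation.

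Before the data were examined, 30 gene lists, the size rule, the processing alternatives and the rule for named genes were fixed. The named genes are NAC1, the 12 genes highest and 12 lowest by the interval bound nearest to 1, up to 4 measured members of each list by the same bound, every KDEL cysteine endopeptidase gene, and WOX11, WOX12, WOX5, LBD16 and LBD29. Transposable element and organelle genes were to be left out of the ranking, and 0 of either were called. Only 1 measured gene was marked as a transposable element and all organelle loci were at 0, so these classes were hardly examined. Genes outside the rule are named to spell out small counts or to illustrate families, and were chosen after their values were seen. A list member was kept where the reference gives its locus the symbol written in advance or no symbol, and patterns took every matching symbol, so genes of a family without such a symbol were missed. Each list has its median log2 ratio, with a range for fewer than 6 measured members and an order-statistic interval otherwise, and the percentile of that median among 10000 random lists matched on mean expression in 20 bins. The percentile describes these libraries and is not a test.

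Names, products, transcript length and GC content come from the TAIR10.1 assembly's annotation, in which 32835 of 33602 loci have a matching locus tag. Because the notes name TAIR10, no coordinates are given. Of 20274 measured genes, 99.9% have a length and GC content. Among 142 named genes, 24 overlap another annotated gene, so without a known strand setting their counts are uncertain: NAC1, DXPS1, AT4G04460, LUP1, ORA47, EXT3, PRP4, CESA1, IRX1, IRX3, XCP1, scpl48, NAC042, AIL6, ESB1, ASA1, CYP71A13, LHCB2.3, AUR1, SYP111, HSP17.4, ADH1, GL2 and PP2-A1. A search with blastn 2.17.0 looked for stretches of at least 100 bases with at least 90% identity in another gene. It marked 12 named genes, 7 of them (CAB2, CAB3, LHCB2.2, CYP71A13, CYP82C2, Prx37 and SAUR68) over at least 50% of the transcript. The others, marked over a smaller part, were CYC1BAT, SAG13, VSP1, VSP2 and LUP1. Reads of the marked genes may be split between copies. An identity of 97% was used first, marked 1 gene and was lowered after that was seen. Reads of the transgene and of the native NAC1 gene cannot be told apart in the counts.

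Alternatives were library totals, median-of-ratios size factors from DESeq2 1.42.0 and upper-quartile scaling, other count minimums, other size thresholds, an assumed coefficient of variation of 0.2, a prior count of 5 and unmatched random lists. Removal of trends with GC content and transcript length, lists without members of other protein families, and pectin and peroxidase lists taken by annotated product, were added after the data were seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.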

Results

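RNA sequencing compared leaf explants of a line with estradiol-inducible, tagged NAC1, cultured on B5 medium with estradiol or with the solvent DMSO alone. The design text gives the purpose as finding genes up-regulated by NAC1, a NAC-domain transcription factor, and the series title sets this in the regeneration of wounded explants. Each group has 1 library, with 39799127 gene counts in the control and 48350705 in the estradiol library. A count was present at 22640 loci in the control and 23015 in the estradiol library. THI1 had the highest count in both, at 0.369% and 0.271% of the counts.

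NAC1 (AT1G56010) had 466 counts in the control and 28380 in the estradiol library, 49.4-fold higher with estradiol (95% counting interval 45.1 to 54.3). Reads of the transgene and the native gene were counted together, and the locus overlaps other annotated genes. CEP1 and CEP2, which encode cysteine endopeptidases with a KDEL retention signal, were almost absent from the control library and well above the floor in the estradiol library. By the size rule 11 of 12 immune and salicylate genes, 5 of 8 developmental cell death genes and 9 of 23 xyloglucan endotransglucosylase genes were higher. On the lower side were 8 of 25 light-harvesting and Rubisco small subunit genes, 5 of 8 glucosinolate genes, 15 of 82 auxin-responsive genes and 6 of 21 expansin genes. Of 20274 measured genes, 1090 (5.38%) were higher and 940 (4.64%) lower by the size rule, and 18244 were neither. Counting error alone enters these calls, and with a coefficient of variation of 0.2 assumed between libraries (the assumed variation below) 647 were higher and 357 lower. The genes called higher took 1.51% of the control counts and 5.41% of the estradiol counts, and those called lower 3.99% and 1.40%. At the extremes, 116 genes had an interval wholly above 16-fold and 7 wholly below its inverse.

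**Figure D1:**
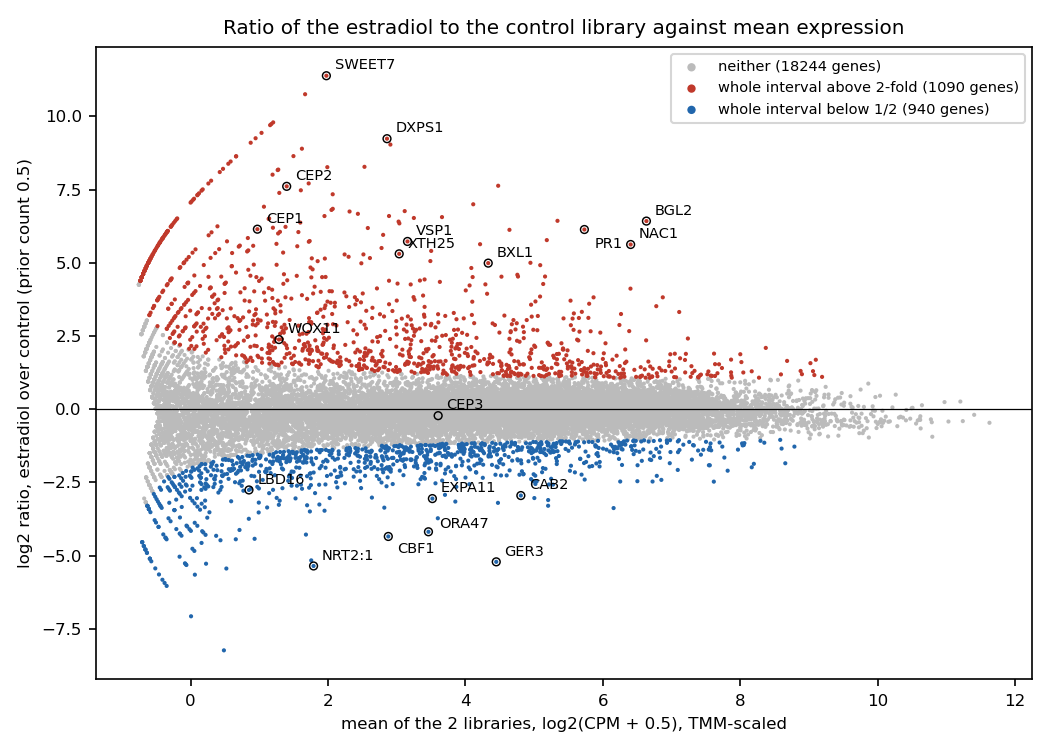
Each point is 1 of 20274 measured genes, with the mean of both libraries in log2(CPM + 0.5) on the horizontal axis and the log2 ratio of estradiol to control on the vertical axis. Red points are the 1090 genes called higher, blue points the 940 called lower and grey points the rest, and circled genes are named in the text.

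The 12 highest genes included transporters, oxidative enzymes and a hormone receptor. SWEET7, of a family of sugar transporters, had 0 counts in the control and 1483 in the estradiol library. Against the floor of 3 counts it was at least 401-fold higher. EDA36, annotated as a pyridoxal phosphate-dependent transferase, was at least 259-fold higher from 0 to 957 counts, and the glycosyl hydrolase gene AT3G47040 at least 133-fold from 0 to 491. PYL3, of the abscisic acid receptor family, was at least 128-fold higher, and the uncharacterized gene AT1G51035 at least 124-fold, both from 0 control counts. DXPS1, annotated as a 1-deoxy-D-xylulose 5-phosphate synthase, was 659-fold higher (282 to 2031), the caleosin-related gene AT1G70680 566-fold (260 to 1542) and the cytochrome P450 gene CYP82C2 334-fold (153 to 911). AT4G04460, a saposin-like aspartyl protease gene, had 53 and 13074 counts, 200-fold higher (153 to 267). The oxygenase gene AT4G10500 was 354-fold higher (121 to 1719) from 3 control counts. UMAMIT25 and AT1G20180 each had 1 control count, with ratios of 579 (104 to 22920) and 691 (124 to 27310). DXPS1 and AT4G04460 overlap other annotated genes and CYP82C2 has similar copies (at least 90% identity over 100 bases), so their counts are uncertain.

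Among the 12 lowest genes were cold and jasmonate-related transcription factors, peroxidases and a nitrate transporter. GER3, a germin gene, had 4901 counts in the control and 162 in the estradiol library, 37.3-fold lower with estradiol (31.9 to 43.9). NRT2:1, a high-affinity nitrate transporter, was 42.4-fold lower (25.9 to 74.6), and the receptor-like kinase gene AT1G05700 37.0-fold lower (22.9 to 64.1). CBF1 and CBF2, which activate cold-responsive genes, were 20.5-fold (16.1 to 26.7) and 19.9-fold lower (13.2 to 31.5), and ORA47, a jasmonate-related ERF-family gene, 18.3-fold lower (15.1 to 22.4). AHL20 was 22.7-fold lower (12.1 to 48.1). Against the floor of 3 counts, the oxygenase gene AT3G46490 (135 and 0 counts) was at least 55.5-fold lower. On the same basis the peroxidase gene AT5G58390 (60 and 0) was at least 24.7-fold lower. LUP1, a lupeol synthase gene, kept 3 counts (51.4-fold lower, 17.2 to 252), the pseudogene AT1G69140 2 counts (49.3-fold, 13.2 to 414) and the peroxidase gene AT4G30170 1 count (77.6-fold, 13.4 to 3114). LUP1 and ORA47 overlap other annotated genes.

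In the list of KDEL cysteine endopeptidases, CEP1 and CEP2 were higher and CEP3 was neither. CEP1 had 3 and 301 counts, 81.4-fold higher (27.6 to 397), and CEP2 had 2 and 590, 239-fold higher (66.0 to 1981). CEP3 was at 497 and 525 counts, a log2 ratio of -0.22. Developmental cell death genes were higher in 5 of 8 measured members, with a median log2 ratio of 2.39 (-0.29 to 6.15, percentile 100). Besides CEP1, these were AT2G14095, written in the list as EXI1 (34.2-fold, 20.9 to 60.2), the nuclease gene BFN1 (14.8-fold, 12.1 to 18.4), scpl48 (11.5-fold, 10.8 to 12.2) and the xylem protease gene XCP1 (log2 ratio 1.26). AT4G04460 was written in that list as PASPA3 and left out, because the reference does not give it that symbol.

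Cell wall lists held calls in both directions. Xyloglucan endotransglucosylase genes, whose products cut and rejoin wall xyloglucan, were higher in 9 of 23 measured members and lower in 2, with a median log2 ratio of 1.06 (-0.12 to 1.69, percentile 100). Under the assumed variation 5 were higher and 2 lower. XTH25 was 40.0-fold higher (29.5 to 55.7), XTH10 20.5-fold (16.7 to 25.3) and XTH24 9.99-fold (9.51 to 10.5), while XTH31 was 8.61-fold lower (7.90 to 9.40) and XTH32 3.96-fold lower (3.49 to 4.51). Expansin genes, which encode wall-loosening proteins, were lower in 6 of 21 and higher in 2, with a median of -0.69 (-1.58 to 0.35, percentile 0), and 4 stayed lower and 1 higher under the assumed variation. EXPA8 was 9.20-fold lower (5.13 to 17.9), EXPA11 8.33-fold (7.12 to 9.80) and EXP3 5.94-fold (5.06 to 6.99). The 2 higher members were EXLA1 (2.42-fold, 2.26 to 2.60) and PNP-A (19.3-fold, 15.3 to 24.7), which belongs to the expansin-like proteins and is known as a plant natriuretic peptide.

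Pectin-modifying enzyme genes listed by symbol were higher in 5 of 22 measured members and lower in 1, with a median of 0.46 (-0.32 to 1.29, percentile 99.97), and 3 stayed higher and 0 lower under the assumed variation. BXL1, a beta-xylosidase gene, was 31.9-fold higher (26.8 to 38.2), PME2 21.3-fold (8.88 to 66.6), ATPMEPCRB 4.10-fold (3.81 to 4.43) and AT2G26440 2.71-fold (2.58 to 2.84), and PME5 was 3.51-fold lower (3.05 to 4.05). The fifth higher member, PLL3, is 1 of 5 POLTERGEIST-like phosphatase genes that share the symbol pattern. Without them 4 of 17 were higher and 1 lower, and the median was 0.21 (percentile 93.6). The balance depends on which loci carry a symbol, since of 105 measured genes with pectin-related products 11 were higher and 21 lower, with a median of -0.36 (-0.53 to -0.08, percentile 0). Of these 105, 5 stayed higher and 11 lower under the assumed variation. Class III peroxidase genes listed by symbol were higher in 3 of 9 and lower in 1, with a median of 0.40 (-0.24 to 1.29, percentile 98.4), but 1 stayed higher and 1 lower under the assumed variation. PRXCA was 6.04-fold higher (4.09 to 9.24), AT2G41480 2.44-fold (2.09 to 2.86) and PRXCB 2.29-fold (2.24 to 2.34), and Prx37, which has similar copies, was 5.95-fold lower (5.49 to 6.46). Without UBP14, a ubiquitin protease gene with PER1 as a synonym, 8 members had a median of 0.68 (percentile 99.8). Of 38 measured genes with a peroxidase product 8 were higher and 10 lower, AT5G58390 and AT4G30170 among the latter, with a median of -0.26 (-0.51 to 0.46, percentile 5.57). Of these 38, 5 stayed higher and 9 lower under the assumed variation.

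Of 36 arabinogalactan protein genes 6 were higher and 7 lower, with a median of -0.14 (-0.96 to 0.28, percentile 10.6). Under the assumed variation 2 of them were higher and 1 lower, and past 4-fold 1 and 0. AGP5 was 12.6-fold higher (9.55 to 17.1) and AGP24 4.64-fold higher (3.38 to 6.49), while AGP41 was 4.16-fold lower (3.35 to 5.20) and FLA1 was at a log2 ratio of -1.80. Of 15 extensin and related genes 5 were measured, with EXT3 2.15-fold higher (2.11 to 2.19) and PRP2 lower at a log2 ratio of -1.49. LRX3 and PRP4 had log2 ratios of 0.77 and -0.93. The extensin median was -0.42 (range -1.49 to 1.10, percentile 9.77) and was 0.77 without the count minimum. None of 5 primary wall cellulose synthase genes was called, with a median of -0.32 (range -0.96 to -0.16, percentile 19.8). CESA5, at -0.96, was the farthest from 0.

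Defence genes were higher in nearly the whole list. Of 12 immune and salicylate genes 11 were higher and none lower, with a median log2 ratio of 2.80 (1.34 to 6.14, percentile 100). BGL2, which encodes the pathogenesis-related glucanase PR2, had 413 and 43808 counts, 86.1-fold higher (78.1 to 95.1), and PR1 was 70.5-fold higher (62.1 to 80.4). CYP71A13, a camalexin synthesis gene with a similar copy, was 86.4-fold higher (58.9 to 133). ALD1, needed for pipecolic acid synthesis, was 32.9-fold higher (14.9 to 90.4). WRKY70 was the member not called, at -0.15. Wound and jasmonate genes were split, with 8 of 29 higher, 2 lower and a median of 0.18 (-0.16 to 0.68, percentile 96.3), or 0.08 (percentile 75.6) with a minimum of 50 counts. Under the assumed variation 5 were higher and 0 lower. TAT3 was 86.8-fold higher (74.3 to 102) and JAZ7 4.45-fold (3.02 to 6.75). The vegetative storage protein genes VSP1 and VSP2 were 53.7-fold (39.2 to 75.6) and 4.61-fold higher (4.24 to 5.01). These 2 genes are similar to each other over part of their transcripts. RRTF1 was lower at a log2 ratio of -1.79 and MYC2 2.08-fold lower (2.01 to 2.16). The jasmonate synthesis genes LOX2, AOS and OPR3 had log2 ratios of 0.26, -0.32 and -0.16.

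Leaf senescence genes were higher in 4 of 11 and lower in 1, with a median of 0.42 (-0.73 to 2.62, percentile 99.3). SAG13, which is similar to another gene over part of its transcript, was 30.3-fold higher (26.6 to 34.7). The chlorophyll breakdown gene NYE1 was 6.13-fold higher (5.74 to 6.56), NAC042 5.43-fold (4.07 to 7.36) and SEN1 4.16-fold (3.66 to 4.75). NAP, a NAC gene of leaf senescence, was 2.64-fold lower (2.35 to 2.96). Across the NAC family apart from NAC1, 12 of 71 were higher and 2, NAP and TIP, lower, with a median of 0.15 (-0.16 to 0.56, percentile 99.1), or 0.03 (percentile 80.1) without the count minimum. NAC074 had 1 and 460 counts, a ratio of 373 (66.7 to 14780), and NAC025 1 and 109, a ratio of 88.5 (15.6 to 3525). NAC084 was 14.5-fold higher (9.01 to 24.7) and NAC016 6.36-fold (4.72 to 8.75).

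Root founder and primordium regulators gave 1 higher and 1 lower gene among 9 measured, with a median of -0.70 (-1.86 to 0.06, percentile 3.495), or -0.33 (percentile 19.3) with a minimum of 50 counts. WOX11, a homeobox gene of root founder cells, had 31 and 201 counts, 5.26-fold higher (3.59 to 7.95). LBD16, an auxin-induced gene of lateral root founders, had 118 and 21, 6.92-fold lower (4.33 to 11.6). WOX5 had 13 and 4 counts and was not called, AIL6 was at -0.70, and WOX12 and LBD29 had at most 1 count in either library. Auxin synthesis genes had ASA1 higher at a log2 ratio of 1.63 and YUC5 6.86-fold lower (4.63 to 10.5) among 10 measured. TSB1 and YUC9 were not called, at 1.01 and 2.53. The auxin synthesis median was 0.42 (-1.22 to 2.53, percentile 95.5) and was -0.04 with a minimum of 50 counts and 0.82 without any. Auxin-responsive genes were lower in 15 of 82 and higher in 3, with a median of -0.42 (-0.70 to -0.15, percentile 0.01). Under the assumed variation 9 were lower and 1, AT4G13790, higher. With a minimum of 50 counts 9 were lower and 1, SAUR36, higher, so no higher call held under both. SAUR68, which has a similar copy, had 41 and 2 counts, 25.3-fold lower (6.56 to 216), AT3G53250 51 and 3, 21.0-fold lower (6.78 to 105), and AT1G29500 57 and 7, a log2 ratio of -3.23. AT4G13790 had 0 and 28 counts, at least 7.57-fold higher, and AT2G28085 and SAUR36 were higher at log2 ratios of 2.20 and 1.30.

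Light-harvesting and Rubisco small subunit genes were lower in 8 of 25 and higher in none, with a median of -0.82 (-1.05 to -0.50, percentile 0), and 5 stayed lower under the assumed variation. CAB2 was 7.74-fold lower (7.02 to 8.54), LHCB2.2 4.83-fold (4.45 to 5.26), LHCB2.3 4.59-fold (4.02 to 5.26) and CAB3 3.96-fold (3.85 to 4.07), all but LHCB2.3 with similar copies. Glucosinolate genes were lower in 5 of 8 and higher in none, with a median of -1.21 (-2.05 to 0.91, percentile 0). Under the assumed variation 1 of the 8 was still lower, and 0 passed a 4-fold threshold. The regulator MYB29 was 4.15-fold lower (3.44 to 5.04), BCAT4 was 2.27-fold lower (2.11 to 2.43), and the aliphatic pathway genes CYP79F1, CYP83A1 and MAM1 were 2.77-fold (2.63 to 2.92), 2.65-fold (2.57 to 2.74) and 2.36-fold lower (2.28 to 2.45). CYP79B2, of the indolic branch, had a log2 ratio of 0.91.

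Abscisic acid and dehydration genes were lower in 5 of 11 and higher in none, with a median of -0.60 (-2.10 to -0.01, percentile 0.1), and 3 stayed lower under the assumed variation. NCED3, which encodes an abscisic acid synthesis enzyme, was 4.81-fold lower (4.36 to 5.30), COR15A 4.30-fold (4.17 to 4.43), LTI78 3.78-fold (3.65 to 3.90), LTI30 3.57-fold (2.93 to 4.38) and ERD10 2.21-fold (2.16 to 2.27). None of 12 cell cycle genes was called, although their median was -0.76 (-0.91 to -0.51, percentile 0.18), with SYP111 at -0.94, AUR1 at -0.91, CYC1BAT at -0.90 and CDC20.1 at -0.85. Circadian clock genes had GI 2.67-fold lower (2.47 to 2.88) as the single call among 10, with a median of -0.58 (-1.41 to -0.14, percentile 0.65), or -0.34 (percentile 6.435) with a minimum of 50 counts. PRR7, PRR5 and CCA1 were at -0.82, -0.88 and -1.08. Flavonoid and anthocyanin genes had FLS1 5.20-fold lower (4.81 to 5.63) and PAP1 4.04-fold lower (3.73 to 4.37) among 9, with TT5 at -0.48, TT7 at 0.19 and a median of -0.13 (-2.01 to 0.12, percentile 19.8).

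Heat shock genes were higher in 5 of 8 and lower in 1, with a median of 1.64 (-1.41 to 5.35, percentile 99.99), and 3 stayed higher and 0 lower under the assumed variation. HSP17.4 was 43.0-fold higher (21.6 to 100.3), HSP17.6A 25.3-fold (14.3 to 49.4) and HSP17.6II 10.1-fold (4.69 to 25.8), and HSFA2 and HSP90.1 were higher at log2 ratios of 1.65 and 1.63. HSP18.2 was 2.66-fold lower (2.01 to 3.55). Xenobiotic detoxification genes were higher in 4 of 27 and lower in 1, with a median of 0.49 (-0.16 to 1.02, percentile 100), and 2 stayed higher and 0 lower under the assumed variation. GSTU3 was 53.2-fold higher (20.5 to 197), GSTU4 5.09-fold (4.73 to 5.47), GSTU9 3.69-fold (2.84 to 4.87) and GSTU11 2.91-fold (2.24 to 3.83), and GSTU20 was 2.94-fold lower (2.84 to 3.04). None of 5 hypoxia genes was called, with LBD41 at 1.01, HB1 at 0.58, ADH1 at -0.07 and AT4G33070 at -0.86. The hypoxia median was 0.16 (range -0.86 to 1.01, percentile 77.4) and was -0.47 without the count minimum.

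Among marker genes of other leaf cell types only 1 xylem gene was called by the size rule. A gene not called may still differ, since few counts widen its interval. Only 3 of 7 measured epidermis and trichome markers and 4 of 5 guard cell and stomatal markers had at least 50 counts. Among 10 xylem and secondary wall markers XCP1 was higher, with IRX1 at -0.64, IRX3 at -0.41, XCP2 at -0.29 and a median of -0.33 (-0.49 to 0.11, percentile 18.1). Phloem markers had a median of -0.25 (range -0.49 to -0.04, percentile 16.8), with PP2-A1 at -0.49, SUC2 and CalS7 at -0.25 and APL at -0.17. Guard cell and stomatal markers had a median of -0.39 (range -0.82 to -0.03, percentile 13.3), with KAT1 at -0.82, MYB60 at -0.75, HT1 at -0.39 and FMA at -0.29. Epidermis and trichome markers had a median of -0.08 (-1.24 to 0.89, percentile 42.4), with PDF1 at -1.24, GL2 at 0.52, ATML1 at -0.24 and KCS10 at -0.08. Of 12 root cell type markers only ESB1 was measured, with 24 and 23 counts and a log2 ratio of -0.36 (-1.25 to 0.53).

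**Figure D2:**
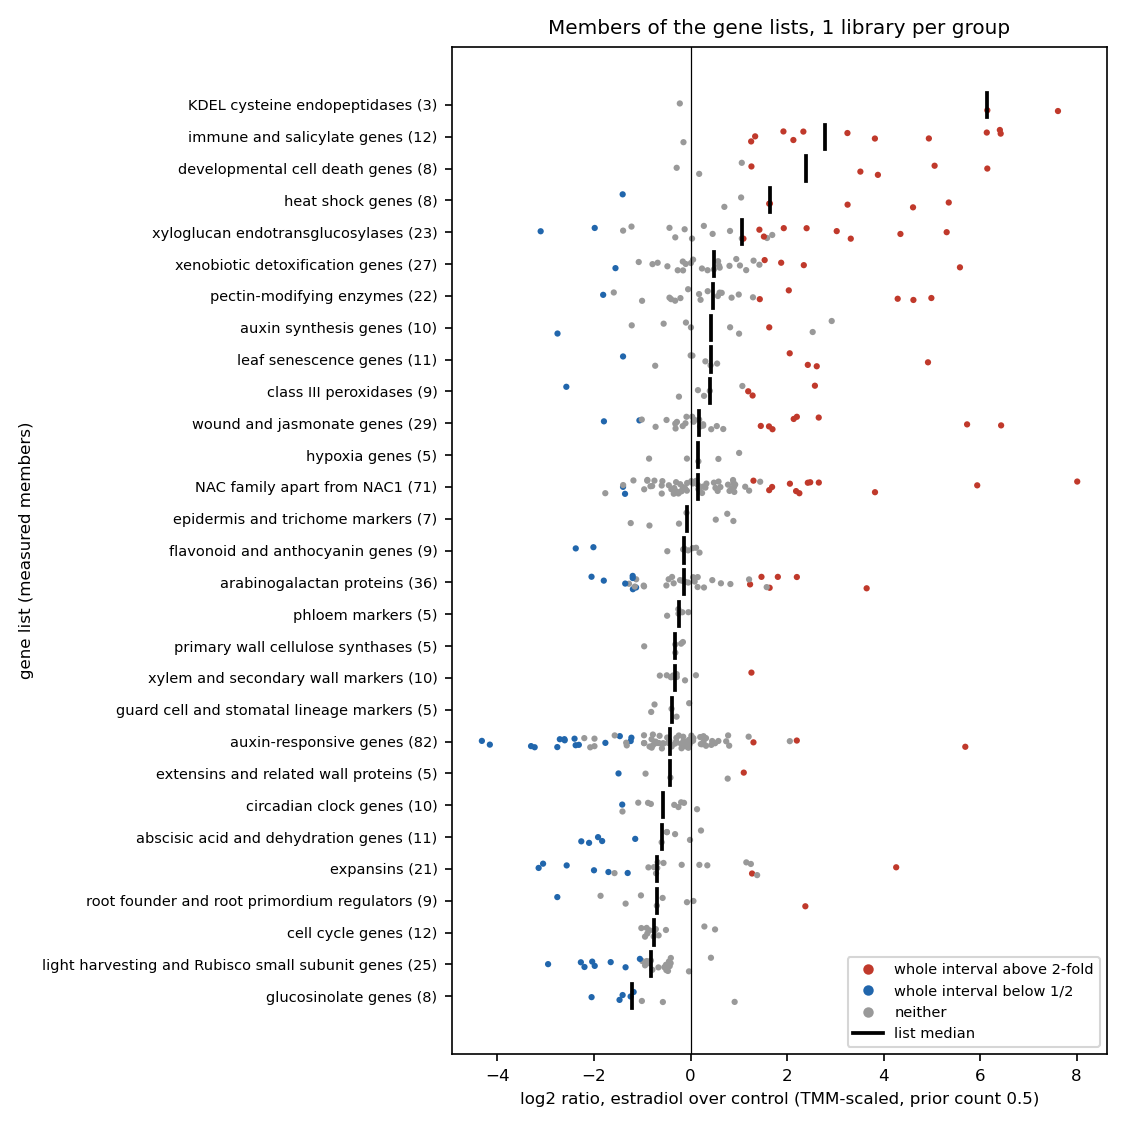
Each point is a measured member of a gene list fixed in advance, placed by its log2 ratio of estradiol to control, and the number of measured members follows the list name. Red and blue points are members called higher and lower, and black bars are list medians, from -1.21 for glucosinolate genes to 6.15 for KDEL cysteine endopeptidases.

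With 1 library per group these ratios have no replicate check, and under the assumed variation the calls of EXLA1, AT2G26440, PLL3, PME5, PRXCB, AT2G41480, FLA1, EXT3, PRP2, XCP1, MYC2, RRTF1, NAP, TIP, ASA1, AT2G28085, SAUR36, CYP79F1, CYP83A1, MAM1, BCAT4, LTI30, ERD10, GI, HSFA2, HSP90.1, HSP18.2, GSTU9, GSTU11 and GSTU20 ended. No library with estradiol and without the transgene was analysed here, and counts of EXT3, scpl48, XCP1, CYP71A13, NAC042, ASA1, LHCB2.3, HSP17.4 and AIL6 are uncertain because they overlap other annotated genes.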

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

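The removal of trends with GC content and transcript length, the lists without members of other protein families, and the pectin and peroxidase lists by annotated product, were chosen only after the results were seen. The counts of called genes depended on how strict the rule was. With the point ratio in place of the interval, 1709 genes were lower and 1587 higher, and with the interval past 4-fold, 161 were lower and 468 higher. With an assumed coefficient of variation of 0.2 between libraries, 357 were lower and 647 higher, and the NAC1 log2 ratio of 5.63 had an interval of 4.82 to 6.44. These differences follow from the thresholds themselves. Scaling moved the counts less, to 1024 to 1115 genes higher and 900 to 1028 lower, and all 1090 higher genes were shared with library totals and median-of-ratios factors. The share of higher genes among the calls ran from 49.9% under upper-quartile scaling to 55.3% under library totals, and the all-gene median log2 ratio from -0.04 to 0.03. MYC2, LHCA4 and HSP18.2 were no longer called under library totals, and under upper-quartile scaling higher calls went from 3 to 1 among auxin-responsive genes (AT2G28085 and SAUR36 ended) and from 9 to 8 among xyloglucan endotransglucosylase genes. With a coefficient of variation of 0.2 no call was left among the extensin, xylem and clock lists, no lower call among the NAC, wound, senescence, pectin, heat shock and xenobiotic lists, and no higher call among auxin synthesis genes. Lower calls then went from 7 to 1 among arabinogalactan protein genes, 5 to 1 among glucosinolate genes, 15 to 9 among auxin-responsive genes, 8 to 5 among light-harvesting genes, 5 to 3 among abscisic acid genes and 6 to 4 among expansins. Higher calls went from 6 to 2 among arabinogalactan protein genes, 3 to 1 among peroxidase and auxin-responsive genes, 2 to 1 among expansins, 4 to 2 among xenobiotic genes, 5 to 3 among heat shock and pectin genes, 8 to 5 among wound genes, 9 to 5 among xyloglucan endotransglucosylase genes, 12 to 9 among NAC genes, 11 to 9 among immune genes and 5 to 4 among cell death genes. Past 4-fold, lower calls were 0 among glucosinolate and arabinogalactan protein genes, 2 among abscisic acid genes, 3 among light-harvesting genes and expansins and 5 among auxin-responsive genes, and higher calls were 7 among immune genes, 5 among NAC genes, 3 among wound genes and 2 among pectin genes. With the trends removed, 1080 genes were higher, 1064 of them shared, and 924 lower, 899 of them shared, and HSP18.2 was not called. Of 30 list medians, 25 kept their sign under each alternative run for them. Lists by annotated product in place of symbol turned pectin genes to -0.363 (11 of 105 higher, 21 lower) and peroxidase genes to -0.260 (8 of 38 higher, 10 lower). The other 3 medians that changed sign were extensins at 0.77 and hypoxia genes at -0.47 without a count minimum, and auxin synthesis genes at -0.04 with at least 50 counts. A count minimum changes only which low-count members enter a median. Measured members went from 5 to 9 for extensins, 5 to 8 for hypoxia genes and 10 to 6 for auxin synthesis genes. Sign aside, the NAC family median went from 0.15 (percentile 99.1) to 0.03 (80.1) without a count minimum and to 0.24 (99.95) with at least 50 counts, and auxin synthesis genes to 0.82 without one. With at least 50 counts the median went to 0.08 (75.6) for wound and jasmonate genes, -0.33 (19.3) for root founder regulators, -0.34 (6.435) for clock genes and 0.37 (88.7) for hypoxia genes. Without members of other families it was 0.21 (93.6) for pectin and 0.68 (99.8) for peroxidase genes. Depth limits genes with few counts, since 10 counts in each library leave an interval of 0.374-fold to 2.68-fold.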

Other observations

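The tally of gene families, the test of reads taken up by higher genes, the resampling interval of the clock genes and the touch-gene median without the CBF paralogue were chosen only after the results were seen.

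Receptor and WRKY transcription factor families, which no list covers as a family, also held many called genes. Among 130 families defined by a shared symbol stem with at least 10 measured members, 11 had a median above percentile 99 of matched random lists and 14 below percentile 1. Some of these, such as XTH, NAC, GSTU and EXPA, repeat the fixed lists. An extreme percentile can go with a small shift where a family is large. The EMB stem, with 157 measured genes, was at percentile 0 with a median of -0.14 and 0 calls. CRR, PTAC and HCF, also below percentile 1, had 0 calls too. Receptor-like protein genes (RLP) were higher in 24 of 49 measured members and lower in 1, with a median log2 ratio of 1.21 (0.46 to 1.94). Genes with the stem CRK, which includes cysteine-rich receptor-like kinases, were higher in 14 of 38 and lower in 3, with a median of 0.53 (0.21 to 1.64), and CRK37 had 8 and 1008 counts and CRK7 26 and 2021. WRKY genes were higher in 16 of 57 and lower in 6, with a median of 0.39 (-0.08 to 0.71), with WRKY38 at 14 and 346 counts and WRKY40 at 7326 and 2744. Protein disulfide isomerase-like genes (PDIL), at percentile 98.8 and so not among the 11, were higher in 4 of 12 and lower in none, with PDIL2-2 at a log2 ratio of 2.01 and PDIL1-2 at 1.74.

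On the lower side, UMAMIT transporter genes were lower in 7 of 33 and higher in 3, with a median of -0.73 (-1.13 to 0.44, percentile 0), and UMAMIT44 was at -1.63 while UMAMIT25 was among the 12 highest genes. MYB genes were lower in 15 of 74 and higher in 7, with a median of -0.39 (-0.62 to 0.18, percentile 0.05), with MYB56 at -2.55 and MYB2 at 4.14. Both intervals include 0.

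The immune and salicylate genes were higher in 11 of 12 members. The tables argue against a trend with GC content or transcript length as the whole cause. The removed trend ran only from -0.13 to 0.15 on the log2 scale, against a list median of 2.80. With it removed 11 members still passed the size rule. So small a correction could hardly have changed that count, which adds no separate support. A difference of plants, culture or estradiol itself and not NAC1 cannot be told apart from NAC1 induction with 1 library per group. A hypothesis is that NAC1 induction, directly or through cell death, may raise salicylate defence. Replicate libraries, together with estradiol without the transgene, would test whether the rise depends on NAC1, but not by which route.

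Light-harvesting genes were lower in 8 of 25 members and glucosinolate genes in 5 of 8, and neither list had a higher call. Genes called higher took 1.51% of the control counts and 5.41% of the estradiol counts. That rise is too small to push other genes down as far as the list medians. The all-gene median log2 ratio under library totals was 0.029, but it could not have come near the list medians by this route and adds no separate support. A trend with GC content or transcript length ran only from -0.13 to 0.15 on the log2 scale, and with it removed the medians were -0.845 for light-harvesting and -1.229 for glucosinolate genes. With a coefficient of variation of 0.2 assumed between libraries, 5 light-harvesting genes and 1 glucosinolate gene stayed lower. An effect of NAC1 or of estradiol, or variation between the 2 libraries, may account for the pattern, and these were not tested apart. Time of day and handling, weighed below for CBF1, CBF2 and ORA47, were not tested for these lists.

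CBF1, CBF2 and ORA47 were 18.3-fold to 20.5-fold lower in the estradiol library. A difference in the time of day at harvest cannot be told apart here, since medians of morning and evening clock genes lay 0.255 apart on the log2 scale, under the 0.5 set in advance as speaking against it, but with a resampling interval of 0.051 to 1.19. Handling before harvest is a candidate explanation, since 10 of 16 other rapidly touch- and wound-induced genes were lower and none higher, with a median of -1.39 (-1.77 to -0.60), or 9 of 15 and -1.24 (-1.75 to -0.60) without DREB1A (CBF3), the paralogue of CBF1 and CBF2. Of the 3 TCH touch genes, however, only TCH2 was lower, at -1.54, while TCH3 at 0.23 and TCH4 at -0.12 were not called. The fixed wound and jasmonate list went both ways, with 8 of 29 genes higher, JAZ7, JAZ8 and JAZ10 among them, and 2 lower. TCH2, TCH3, WRKY40, MYBR1 and DREB1A overlap other annotated genes, as do the clock genes RVE1, PCL1, ELF3 and BOA, so their counts are uncertain. The set was written by hand outside the fixed lists and many members also respond to wounding and defence, so handling, NAC1 and estradiol are not separated and the cause stays open.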
